A study of Homo sapiens with 12 samples.

How the data were processed

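Small RNA of AC16 cells, an established human cardiomyocyte-derived line, and of exosomes isolated from them was sequenced in 12 libraries. The 4 groups were whole cells named Con, whole cells named Ang, exosomes named Con and exosomes named Ang, with 3 libraries each. The column headers of the 6 Ang files read AngII. The name is not spelled out, and the dose and time are not given in the sources used here. No source states whether the numbered replicates are separate cultures, so the p-values measure only the spread between these samples. Per the labels' protocols, cell RNA was extracted with the miRNeasy Micro kit, exosomes were isolated and their RNA extracted with the exoRNeasy Maxi kit, and libraries were made with the QIAseq miRNA kit.

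The deposited values are raw counts of unique molecular identifiers (UMIs) per mature miRNA name, per the file headers, in whole numbers with no normalization. Per the submitters' processing notes, cutadapt was used and the genome build was GRCh38. The aligner, the mismatches allowed, the miRNA annotation and the counting program are not given in the sources used here. Reads of near-identical family members, such as those of let-7 or miR-320, could therefore have been split between names, and values of single members are uncertain for that reason. The cell files hold 2656 names and the exosome files 2580. The 76 names absent from the exosome files never exceeded 20 counts in a cell library and were taken as 0 in exosomes. Totals ran from 413513 to 528844 UMIs in cell libraries and from 697049 to 1029883 in exosome libraries. A floor of 3 counts came to between 2.91 and 7.25 CPM (counts scaled by library total), and it covers counting error only. CPM values were computed from library totals, whereas fold changes used TMM scaling factors.

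Hairpin genes, their GRCh38 coordinates and their host genes were taken from GENCODE release 29, which matched 2576 of the names, or 97.0%. Coordinates are those of the hairpin and are left out for names with several hairpin copies. No mature sequences were at hand, so consensus motifs and RNA-binding proteins were not analysed here.

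Each comparison of 2 groups was fitted to its 6 libraries with edgeR 4.0.16 in R 4.3.3. The fit used filterByExpr, TMM scaling, a quasi-likelihood test (robust option off, two-sided) and Benjamini-Hochberg adjustment over all tested names, with an adjusted p threshold of 0.05. The interaction of Ang with compartment, the Ang over Con change in exosomes minus that in cells, was fitted to all 12 libraries. An adjusted p without another name beside it comes from this edgeR fit with Benjamini-Hochberg adjustment. The test was checked on simulated counts with 200 changed names per comparison, as many raised as lowered. For Ang against Con in exosomes it recovered 44% of the names changed 1.5-fold and 84% of those changed 2-fold, and 52% and 82% in cells. It recovered 55% and 78% for exosomes against cells in Con, 44% and 76% in Ang, and 15% and 36% for the interaction. In a comparison of 2 groups the simulated groups otherwise shared a mean profile. The check therefore does not cover the large scaling shift between exosomes and cells. It also gave every tested name the spread of the fitted trend and included no outlying library. Recovery of names with a larger spread was not checked.

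Lists of miRNAs, fixed before the data were examined, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, if at least 3 members were tested, with Benjamini-Hochberg adjustment over lists. The lists were muscle miRNAs, miRNAs described as promoting and as opposing cardiac hypertrophy, fibrosis miRNAs, blood cell, liver, endothelial, neuronal and epithelial markers, and entries that overlap fragments of other RNAs. Others were the let-7, miR-17, miR-29, miR-30, miR-15/16, miR-34 and miR-320 families, the miR-23/27/24 clusters, the miR-221 and miR-222 cluster, inflammation and hypoxia miRNAs, the imprinted chromosome 14 cluster, the chromosome 19 cluster, mirtrons and other Drosha-independent miRNAs, and miRNAs often described in exosomes. All come from general knowledge and share members. Counts of members are also given adjusted over the list alone.

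Named miRNAs were chosen by a rule set before the data were examined. It took the 10 largest changes each way among names past the threshold, with a mean of at least 10 CPM and, outside the interaction, no overlap between the groups. It added the 5 most abundant names of each group and 2 to 4 list members with the lowest p. Of the list members, mostly those past the threshold are printed. Library composition was compared with exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1.

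The alternatives set before the data were examined were RLE size factors, library totals alone, DESeq2 1.42.0, limma-voom, no count filter, a minimum mean of 10 CPM, a replicate block, each library left out in turn, all 12 libraries in each fit, an estimated correlation in camera, list members of at least 10 CPM, detection at 10 counts, and counts thinned to the smallest total. Chosen after seeing the data were removal of a trend on the GC content of the hairpin arm, removal of miR-552-3p and miR-3972, thinned counts in the fits, removal of the names absent from the exosome files, library totals in camera, and removal of 2 libraries together. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1 served for tables and exact tests.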

Results

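The libraries held UMI counts of mature miRNAs from AC16 cells and their exosomes, in 4 groups of 3: cells Con, cells Ang, exosomes Con and exosomes Ang. The study set out to find miRNAs that differ in exosomes of hypertrophic cardiomyocytes. Library totals averaged 489634 ± 57166 UMIs (SD, n = 3) in cells Con, 472289 ± 52111 in cells Ang, 963231 ± 71026 in exosomes Con and 892370 ± 172250 in exosomes Ang. Of the 2656 names listed, cell libraries held 2602 ± 13.0 with a count in Con and 2604 ± 17.8 in Ang. Exosome libraries held fewer, 2287 ± 22.6 in Con and 2214 ± 60.6 in Ang. Nearly every listed name thus had counts in each cell library. Whether reads of other RNAs were counted under some of these names, abundant ones included, is not settled here.

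In cells, let-7a-5p led with 50160 ± 3851 CPM in Con (SD, n = 3), followed by miR-16-5p at 33290 ± 2043, miR-21-5p at 26380 ± 1186, miR-510-3p at 23010 ± 1339 and miR-125b-5p at 21340 ± 580. Exosomes had other leading names. miR-552-3p, encoded on chromosome 1 at 34669599 to 34669694 outside any annotated host gene, reached 87430 ± 2439 CPM in exosomes Con and 150500 ± 5207 in exosomes Ang, against 64.0 ± 8.36 and 92.2 ± 12.6 in the cells. miR-3972, in an intron of PADI3, reached 84210 ± 960 and 140600 ± 5924 CPM in exosomes. Together they held 17.2% ± 0.18 of UMIs in exosomes Con and 29.1% ± 0.088 in exosomes Ang, and under 1% in cells. The 10 leading names held 23.5% ± 0.69 in cells Con, 23.0% ± 0.32 in cells Ang, 39.6% ± 0.69 in exosomes Con and 45.5% ± 0.21 in exosomes Ang. For the latter pair the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Muscle miRNAs, which include miR-1, miR-133a, miR-208 and miR-499a, held 0.040% ± 0.0016 of UMIs in cells Con.

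**Figure D1:**
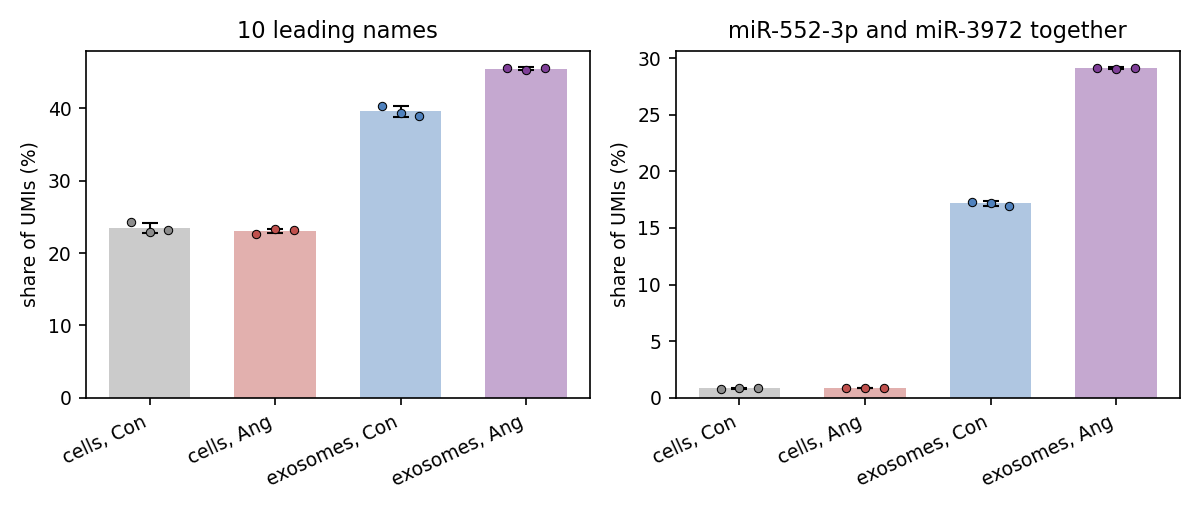
Share of UMIs (%) held by the 10 leading names of each library (left) and by miR-552-3p and miR-3972 together (right), by group; bars are means, error bars SD, points the 3 libraries of a group. The pair held 17.2% of UMIs in exosomes Con and 29.1% in exosomes Ang.

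Ang was first compared with Con in exosomes, the comparison closest to the stated aim. The pair that already led exosomes rose: miR-552-3p 1.93-fold (log2 0.95, SE 0.061, adjusted p = 2.54e-06, n = 3 per group) and miR-3972 1.87-fold (log2 0.91, SE 0.061). Among names of lower abundance, miR-519c-3p of the primate-specific chromosome 19 cluster rose 2.70-fold, from 48.6 ± 4.48 to 118 ± 14.7 CPM, and miR-23a-5p rose 2.39-fold, from 83.2 ± 9.46 to 177 ± 1.11 CPM. miR-3614-3p, from the gene of the antiviral ubiquitin ligase TRIM25, rose 2.35-fold to 2242 ± 209 CPM. miR-6805-3p, from the ribosomal protein gene RPL28, rose 2.31-fold to 2670 ± 207 CPM, and miR-6816-3p rose 2.26-fold.

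Among names whose groups did not overlap, the deepest falls in exosomes were those of miR-450a-2-3p, 7.10-fold lower (173 ± 17.9 to 21.7 ± 3.51 CPM, log2 -2.83, SE 0.169, adjusted p = 2.21e-06), miR-1285-3p, 5.24-fold lower, and miR-4699-3p, 4.10-fold lower (1838 ± 63.0 to 399 ± 20.9 CPM). The abundant miR-887-3p, in an intron of FBXL7 on chromosome 5 at 15935182 to 15935260, fell 3.09-fold from 14200 ± 250 to 4097 ± 168 CPM (log2 -1.63, SE 0.053, adjusted p = 6.87e-08). miR-554, miR-3141 and miR-382-5p fell 2.76-fold, 2.66-fold and 2.54-fold. Of the other leading exosome names, miR-3944-5p (log2 -0.38), miR-671-3p (-0.42) and miR-5008-3p (-0.36, a call that ended in a fit to all 12 libraries) fell slightly, and miR-6785-3p did not pass (log2 0.18, SE 0.074, adjusted p = 0.0934). In all, 408 of 1199 tested names passed, with 203 higher and 205 lower in Ang, and 69 of them changed at least 2-fold. In CPM by library totals, the groups did not overlap for 52.4% of tested names, where chance gives 10%. That share includes any shift between library totals and the TMM scale. With library totals in place of TMM, 151 were higher and 319 lower, as the median of all names moved by -0.16; DESeq2 gave 177 and 116.

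**Figure D2:**
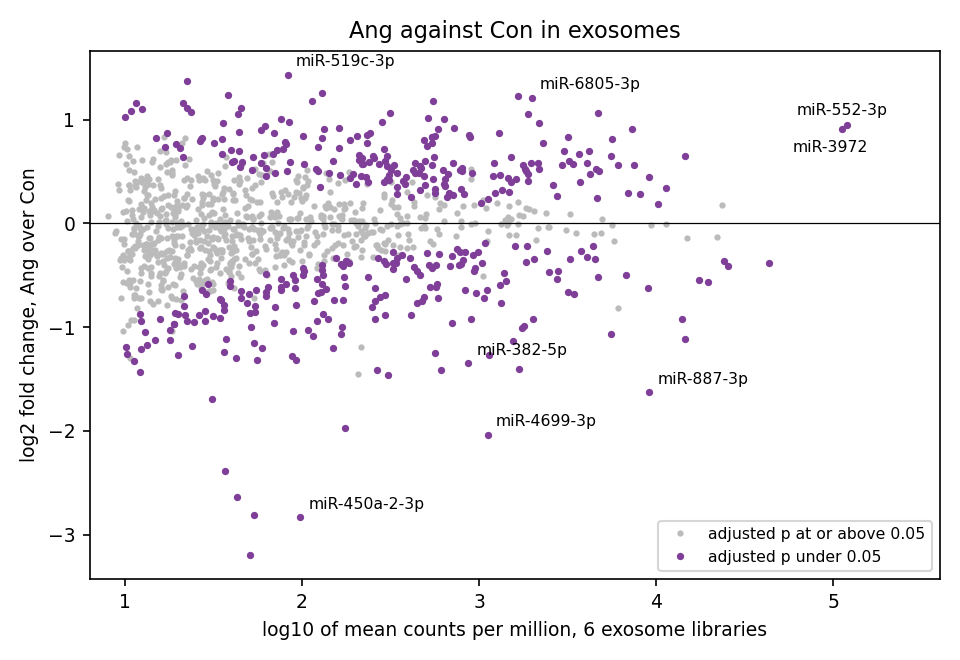
Log2 fold change of Ang over Con in exosomes against the log10 of mean CPM over the 6 exosome libraries; each point is a tested miRNA name, coloured where the adjusted p was under 0.05. miR-552-3p and miR-3972 stand at the right with log2 changes of 0.95 and 0.91, and miR-450a-2-3p is at -2.83.

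Within the lists, members of the miR-23/27/24 clusters, which act in muscle and vessel growth, rose in exosomes: 3 of 7 tested members passed and none fell, namely miR-23a-5p, miR-27b-3p (1.51-fold) and miR-27a-3p (1.64-fold). The same counts held adjusted over the list alone, and the camera test gave adjusted p = 0.273 (adjusted p = 0.959 with an estimated correlation). With library totals 2 of them passed. Of the chromosome 19 cluster, 3 of 6 rose and 2 fell, with miR-519d-3p 1.70-fold lower. Of the imprinted chromosome 14 cluster, 4 of 40 rose and 3 fell: miR-487a-3p rose 2.59-fold, miR-654-5p 1.59-fold (3047 ± 223 to 4322 ± 74.6 CPM) and miR-369-5p 1.38-fold, while miR-382-5p fell from 1289 ± 88.6 to 452 ± 50.2 CPM. Of entries that overlap fragments of other RNAs, 3 of 20 rose and 6 fell. miR-3960 fell 2.09-fold (7834 ± 384 to 3340 ± 189 CPM), miR-3648 2.37-fold and miR-4488 1.54-fold, while miR-7704 rose 1.52-fold. For these entries 4 rose and 7 fell adjusted over the list alone, and counts were unchanged for both chromosomal clusters. With library totals the balance moved to 3 higher and 5 lower for the chromosome 14 cluster and to 2 and 11 for the fragment entries.

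Of miRNAs described as promoting hypertrophy, 2 of 14 rose in exosomes, miR-214-3p (1.39-fold, a call that ended with counts thinned to one total) and miR-27b-3p, and miR-212-3p fell (2.18-fold, 21.2 ± 2.62 to 8.61 ± 0.788 CPM). Of those described as opposing it, 2 of 11 fell, miR-223-3p (log2 -0.45) and miR-142-3p (log2 -1.69), and 0 passed adjusted over the list alone. The fibrosis list had 1 of 13 higher, the same miR-214-3p, and the inflammation and hypoxia list had miR-210-3p, the hypoxia miRNA, higher (1.65-fold) and miR-212-3p lower among 5. Blood cell markers fell for 3 of 7: the red cell miR-451a (log2 -2.63, SE 0.878, adjusted p = 0.0426), miR-223-3p and miR-142-3p. Liver markers had miR-122-5p lower (log2 -2.81, SE 0.835, adjusted p = 0.0262) and miR-885-5p higher (log2 0.82) among 3. Of names often described in exosomes, 4 of 14 fell, miR-423-5p (log2 -1.42) and the blood and liver markers miR-122-5p, miR-451a and miR-223-3p, and 0 passed adjusted over the list alone. Mirtrons were split: of 10, 2 rose and 3 fell, with miR-1234-3p 1.58-fold higher and miR-1229-3p 1.83-fold lower. One let-7 member of 8, let-7c-5p (log2 -1.97), and 1 miR-30 member of 5, miR-30a-3p, fell. Apart from the lists whose change is given, counts adjusted over the list alone were the same.

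Exosomes Con replicate 1 stood apart from the other Con replicates, with a chi-square per degree of freedom over names of 8.04 and 13.0 against them and of 2.16 between them. miR-16-5p stood at 2694 CPM in it against 9752 and 11810, let-7a-5p at 1376 against 2425 and 3168, and miR-21-5p at 489 against 789 and 1082. The fallen blood and liver markers were uneven in the same way. miR-451a stood at 9.71 CPM in replicate 1 against 92.3 and 128 in the other replicates, miR-122-5p at 8.74 against 123 and 157, and let-7c-5p at 66.0 against 368 and 430. In the exosomes Ang libraries miR-451a stood at 0, 23.0 and 6.85 CPM, miR-122-5p at 4.30, 18.8 and 10.8, and let-7c-5p at 41.6, 72.1 and 76.3. For these names Con replicate 1 lay within the Ang range, so their falls rested on Con replicates 2 and 3. For let-7a-5p and miR-21-5p it lay below every Ang library. The calls of miR-451a, miR-122-5p, miR-142-3p, miR-223-3p, let-7c-5p and miR-423-5p each ended when exosomes Con replicate 2 or 3, or one of several Ang replicates, was left out. miR-210-3p lost its call without any library but exosomes Con replicate 1, miR-27a-3p without Con replicate 2 or any Ang replicate, and miR-885-5p without Con replicate 3 or Ang replicate 2. Other fits also ended calls: limma-voom those of miR-451a, miR-122-5p, miR-142-3p, miR-223-3p, let-7c-5p and miR-423-5p, DESeq2 those of miR-451a, miR-885-5p, miR-210-3p and miR-423-5p, library totals those of miR-27a-3p and miR-210-3p, and thinned counts that of miR-27a-3p. No tested member of the miR-221 and miR-222 cluster or of the muscle, endothelial, neuronal, epithelial, miR-17, miR-29, miR-15/16, miR-34 or miR-320 lists passed in exosomes. No list passed camera in this comparison, where adjusted p ran from 0.273 to 0.922 (adjusted p = 0.959 with an estimated correlation). With RLE size factors 0 hypertrophy-opposing and 1 blood cell member fell. The median turned below 0 for the miR-17, miR-15/16 and inflammation lists with library totals, and above 0 for the miR-30 and miR-320 lists with RLE size factors. The liver, miR-17 and miR-15/16 lists had a median and a camera direction above 0 and a mean below 0, and the miR-320 list a median below 0 against a mean and direction above it.

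Ang against Con was then compared in the cells, where changes were fewer and smaller. miR-3922-5p, in an intron of the chondroitin sulfotransferase gene CHST11 on chromosome 12 at 104591633 to 104591716, rose 2.24-fold from 155 ± 11.7 to 352 ± 29.3 CPM (log2 1.16, SE 0.123, adjusted p = 9.38e-05, n = 3 per group). miR-1246 rose 1.99-fold, from 169 ± 16.9 to 337 ± 22.9 CPM, and miR-506-3p, on the X chromosome, rose 1.67-fold to 712 ± 33.4 CPM. miR-320d fell 2.08-fold, from 105 ± 4.74 to 51.2 ± 6.61 CPM, and miR-320c 1.75-fold. miR-8064, miR-3170 and miR-5582-3p fell 1.66-fold, 1.66-fold and 1.63-fold, the last from 939 ± 77.7 to 582 ± 32.2 CPM.

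Of the most abundant names in cells, miR-510-3p fell 1.34-fold to 17280 ± 1980 CPM (log2 -0.43, adjusted p = 0.00375). miR-16-5p (log2 0.21), miR-21-5p (0.14), miR-125b-5p (-0.07) and let-7a-5p (0.01) did not pass, and the sign for let-7a-5p turned with RLE size factors. In all, 107 of 1630 tested names passed in cells, 45 higher and 62 lower in Ang, and 4 changed at least 2-fold. Of the names past the threshold, miR-126-3p had the largest rise (log2 2.46, SE 0.697, adjusted p = 0.0445), which rested on Ang replicate 2 at 4007 CPM against 302 and 318 in the other Ang replicates, and its call ended without that library or any Con replicate, with limma-voom and in a fit to all 12 libraries. The count was 38 without Con replicate 2, 38 without Con replicate 3, and 70 without Ang replicate 1. The calls of miR-7160-5p (log2 0.96) and miR-4731-3p (log2 -1.14) also ended when a library was left out, whereas those of miR-3922-5p, miR-1246, miR-506-3p, miR-320d, miR-320c, miR-8064, miR-3170 and miR-5582-3p held throughout.

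In the cells 2 of 5 miR-320 members, a family made without Drosha, fell, miR-320c and miR-320d, in both counts, with camera adjusted p = 0.108 (adjusted p = 0.937 with an estimated correlation, adjusted p = 0.0173 with a replicate block). Their near-identical sequences leave the split between members uncertain. Of entries that overlap fragments of other RNAs, 3 of 20 rose and none fell: miR-1246, miR-1260a (1.21-fold, 3448 ± 120 to 4196 ± 189 CPM) and miR-7704 (1.25-fold). Adjusted over the list alone, 4 rose. The calls of miR-1260a and miR-7704 ended when Ang replicate 1 or Con replicate 2 or 3 was left out, as did that of miR-519c-3p, and those of miR-1260a and miR-7704 also in a fit to all 12 libraries. Of the chromosome 14 cluster, 2 of 52 fell, miR-433-3p (1.52-fold) and miR-127-3p (1.21-fold, 4243 ± 112 to 3540 ± 161 CPM), and of the chromosome 19 cluster 1 of 9, miR-519c-3p (1.22-fold). miR-208a-3p, from an intron of the cardiac myosin gene MYH6, fell 1.38-fold from 221 ± 26.7 to 162 ± 13.8 CPM, 1 of 4 muscle and 1 of 18 hypertrophy-promoting members. Its call ended without any library but Ang replicate 3, with DESeq2 and with library totals, that of miR-127-3p without Ang replicate 1 or any Con replicate, and that of miR-433-3p without Con replicate 2 or 3. Of names often described in exosomes, miR-1246 rose and miR-320c fell among 13.

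Blood cell markers in cells did not pass over all names, 0 of 5, although 2 did adjusted over the list alone; miR-142-3p had log2 2.62 (SE 0.815, adjusted p = 0.0736) and miR-486-5p log2 2.47 (SE 0.893, adjusted p = 0.123). Both followed Ang replicate 2, where miR-142-3p stood at 2041 CPM against 99.9 and 105 in the other Ang replicates and miR-486-5p at 929 against 30.6 and 37.1. Without that library their log2 changes were -0.25 and -0.77. Of the endothelial pair, miR-126-3p passed. No member passed of the miR-221 and miR-222 cluster, nor on the hypertrophy-opposing, fibrosis, liver, neuronal, epithelial, let-7, miR-17, miR-29, miR-30, miR-15/16, miR-23/27/24, miR-34, inflammation or mirtron lists. Adjusted over the list alone, the hypertrophy-opposing list had 2 higher (miR-9-5p and miR-142-3p, the latter carried by Ang replicate 2), the neuronal and inflammation lists 1 higher each, the exosome list 4 higher (among them miR-486-5p, carried by the same library) and 1 lower, the fibrosis list 1 lower and the hypertrophy-promoting list 2 lower. No list passed camera in cells, where adjusted p ran from 0.108 to 0.992 (adjusted p = 0.937 to 0.992 with an estimated correlation). With a replicate block 5 lists did, as given below. For the hypertrophy-promoting, mirtron and chromosome 19 lists the median and mean differed in sign, or the camera direction differed from them. The near-zero medians of the miR-34 list (with RLE size factors) and of the chromosome 14 and mirtron lists (with library totals) changed sign.

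**Figure D3:**
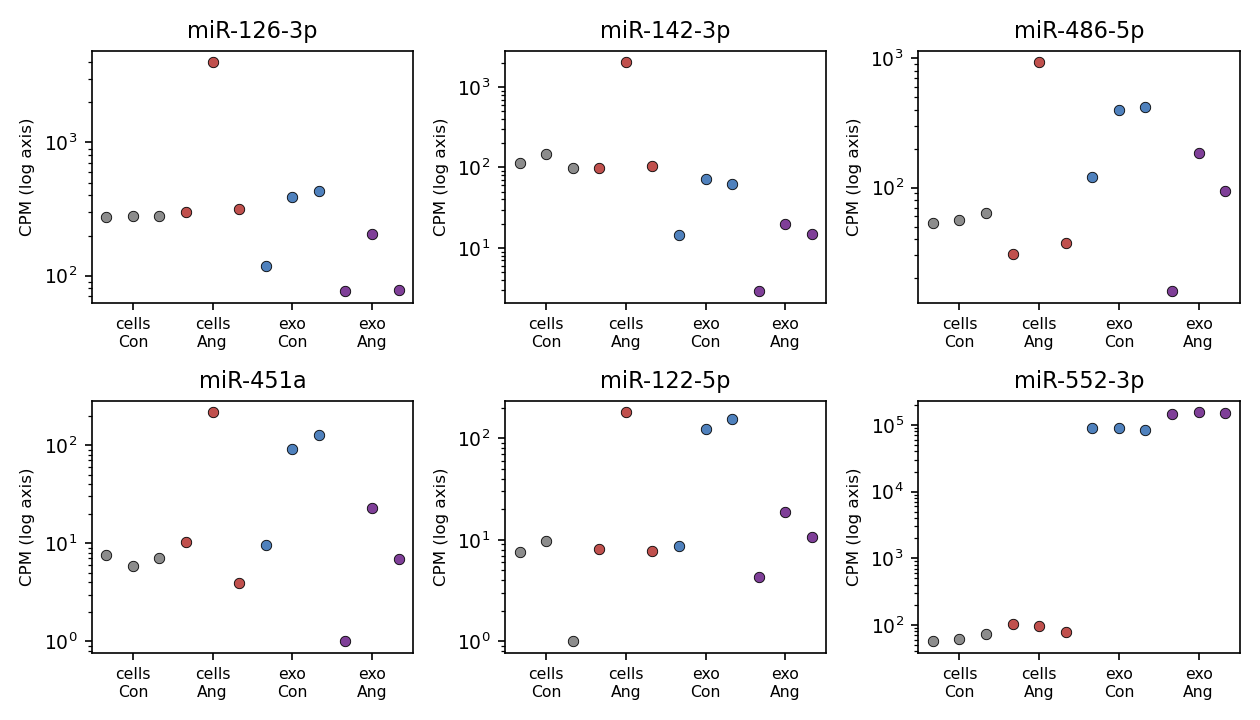
CPM on a log axis of 5 blood, liver and endothelial miRNAs and of miR-552-3p, chosen after their values were seen, with each point a library and 3 libraries per group; a CPM of 0 is drawn at 1. In cells Ang replicate 2, miR-126-3p stands at 4007 CPM and miR-142-3p at 2041, while miR-552-3p is at 96.7.

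Exosomes were next compared with cells in Con, which asks which miRNAs are relatively abundant in exosomes of the Con group. Cell and exosome RNA came from different extraction kits, in Con and in Ang alike. A difference between compartments therefore cannot be told apart from one between kits. miR-552-3p stood highest, with a log2 difference of 11.94 (SE 0.091, adjusted p = 1.99e-14, n = 3 per group). miR-5008-3p, in an intron of WNT9A, followed with log2 9.11 (147 ± 45.3 CPM in cells, 28400 ± 1043 in exosomes), then miR-6785-3p with 8.24, miR-4638-3p with 7.75 and miR-671-3p with 7.47 (486 ± 8.90 and 30240 ± 595 CPM). Names lower in exosomes included those that led in cells: miR-21-5p was 11.8-fold lower in exosomes (26380 ± 1186 and 787 ± 296 CPM), let-7a-5p 7.57-fold, miR-125b-5p 4.22-fold and miR-510-3p 6.07-fold lower. miR-16-5p did not pass (log2 -0.53, SE 0.385, adjusted p = 0.221), and its log2 difference was -0.11 without exosomes Con replicate 1 and -0.98 without replicate 3, where it passed.

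Several names of cells were almost absent from exosomes Con. miR-5582-3p had 1371 counts in the cell libraries and 7 in the exosome libraries, a ratio of 134 on the TMM scale (95% interval 64.8 to 334). miR-759 had 775 and 5 counts, a ratio of 106 (45.2 to 327). Both intervals come from counts summed over the libraries of a group and cover counting error only, not the spread between libraries. miR-33a-5p, which lies in an intron of the sterol regulator gene SREBF2, had 48 counts in cells and 0 in exosomes, at least 3.62-fold lower on the same scale against a floor of 3 counts in each exosome library, or 10.4-fold in CPM by library totals. In all, 1425 of 1710 names passed, 670 higher and 755 lower in exosomes, and 1232 differed at least 2-fold. Directions are relative to TMM scaling: with library totals alone the median of all names moved by -1.52, and 346 names were higher and 1156 lower. In CPM by library totals, which carry this shift, the groups did not overlap for 89.1% of tested names, where chance gives 10%. That share is therefore not a measure of the calls on the TMM scale.

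In exosomes Con several lists passed camera as lower than in cells under TMM scaling. In the miR-23/27/24 clusters 10 of 11 members were lower and miR-23a-5p was higher, with miR-27b-3p at 1241 ± 39.1 CPM in cells and 72.7 ± 4.91 in exosomes. Of the miR-17 family and its clusters, which promote the cell cycle, 13 of 14 were lower, with miR-19b-3p 18.7-fold and miR-20a-5p 16.5-fold lower. In the let-7 family 8 of 9 were lower and let-7c-5p higher, in the miR-30 family 8 of 9 lower and miR-30a-3p higher (miR-30e-5p 8.20-fold lower), and in the miR-15/16 family 6 of 10 lower (miR-424-5p 33.5-fold). Hypertrophy-promoting members were lower for 15 of 19 and higher for 2, with miR-199b-5p 22.1-fold lower. Fibrosis members were lower for 11 of 13 and higher for 1, with miR-29b-3p 17.1-fold lower (2629 ± 278 and 54.2 ± 29.6 CPM). Of the chromosome 14 cluster 38 of 53 were lower and 11 higher, among the latter miR-668-3p (log2 3.06, 8301 ± 69.5 and 24290 ± 1145 CPM) and miR-370-3p (2.63). Counts adjusted over the list alone were the same for these lists. With library totals no let-7, miR-30, hypertrophy-promoting or fibrosis member was higher, so let-7c-5p and miR-30a-3p were no longer called higher. The chromosome 14 cluster then had 7 higher and 45 lower. let-7c-5p was also uneven, at 66.0 CPM in exosomes Con replicate 1 against 368 and 430 in the other Con replicates. Their camera adjusted p ran from 0.0143 to 0.0487, and none held with an estimated correlation, where adjusted p = 0.526 to 0.572, or with library totals, where the lowest adjusted p was 0.0685. With RLE size factors the miR-30 (adjusted p = 0.0502) and miR-15/16 (adjusted p = 0.0516) lists did not pass. Nor did they pass camera with a replicate block (adjusted p = 0.0584 and adjusted p = 0.0612).

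Entries that overlap fragments of other RNAs were higher in exosomes for 13 of 21 and lower for 5 in both counts, with miR-3960 16.9-fold and miR-4516 34.1-fold higher, though library totals gave 9 and 9. Camera gave adjusted p = 0.0487 for them (adjusted p = 0.526 with an estimated correlation). Mirtrons were higher for 7 of 11 and lower for 2 (5 and 4 with library totals), with miR-1236-3p 8.36-fold and miR-877-3p 4.99-fold higher and camera adjusted p = 0.121. Of names often described in exosomes, 3 of 13 were higher, miR-1290 (8.09-fold), miR-1246 (6.52-fold) and miR-486-5p (15.5-fold), and 6 were lower, or 5 adjusted over the list alone. Blood cell markers were higher for 2 of 6 and lower for 2, or 1 adjusted over the list alone, and their median turned below 0 with library totals. Of the endothelial pair, miR-126-3p was higher (log2 1.68) and miR-126-5p lower (-1.86). The call of miR-126-3p ended with library totals (log2 0.16).

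The remaining lists did not pass camera for exosomes against cells in Con. The hypertrophy-opposing list had 9 of 14 lower and 1 higher, the miR-29 family 6 of 7 lower and 1 higher, the cluster of miR-221 and miR-222 4 of 4 (miR-221-3p 4.38-fold), the miR-34 family 5 of 5 (miR-34a-5p 4.38-fold), the inflammation list 5 of 7 lower and 1 higher, the miR-320 family 4 of 5 lower and the muscle list 3 of 4. Adjusted over the list alone, these counts differed only for the hypertrophy-opposing list (8 lower) and the muscle list (2 lower). Liver markers were higher for 1 of 3 and lower for 2, neuronal ones higher for 2 of 6 and lower for 3, epithelial ones higher for 2 of 3 and lower for 1, and the chromosome 19 cluster higher for 3 of 10 and lower for 3. With library totals no liver, neuronal or epithelial marker was higher, and the chromosome 19 cluster had 1 higher and 8 lower. Camera adjusted p for lists not past the threshold ran from 0.0637 to 0.989. For the epithelial, chromosome 19 and exosome lists the median and mean differed in sign.

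The same comparison in Ang gave a like picture. miR-552-3p again stood highest (log2 12.56, SE 0.183, adjusted p = 1.46e-18, n = 3 per group), with miR-5008-3p at 8.82, miR-6785-3p at 8.69 and miR-4638-3p at 8.42. miR-3972 differed by 5.94 and miR-3944-5p by 6.26. miR-21-5p was 7.87-fold, let-7a-5p 6.93-fold, miR-125b-5p 3.57-fold and miR-16-5p 2.58-fold lower in exosomes. miR-26a-2-3p, from an intron of CTDSP2, had 913 counts in cells and 1 in exosomes, a ratio of 462 on the TMM scale (95% interval 82.7 to 18300, counting error only). In all, 1355 of 1627 names passed, 621 higher and 734 lower, or 294 and 1176 with library totals, which moved the median of all names by -1.89. Removal of a GC trend turned miR-510-3p from log2 -0.92 to 0.43 and ended the call of miR-16-5p. Of 1572 names tested in both Con and Ang, 582 were higher in exosomes in both (248.9 for independent lists) and 640 lower in both (314.4), with Pearson r = 0.957 and Spearman rho = 0.962 across names, which are not independent replicates.

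List members in Ang moved as follows between exosomes and cells. All 9 let-7 members were lower (let-7f-5p 7.23-fold), as were 13 of 14 of the miR-17 list, 8 of 9 miR-30 (miR-30a-5p 5.35-fold), 9 of 10 miR-15/16, 10 of 11 miR-23/27/24 (1 higher), 15 of 18 hypertrophy-promoting (1 higher), 11 of 13 hypertrophy-opposing (miR-101-3p 17.3-fold), 11 of 13 fibrosis (1 higher), 34 of 51 chromosome 14 (11 higher) and all 6 inflammation members, the last including miR-155-5p (2.63-fold, a call that removal of a GC trend ended). Entries that overlap fragments of other RNAs were higher for 13 of 21 and lower for 7, or 7 and 11 with library totals. Those 11 lists passed camera with adjusted p from 0.00573 to 0.0458, and none held with an estimated correlation, where adjusted p = 0.444 to 0.532, and 2 with library totals. Without a camera call, miR-29 had 5 of 7 lower (1 higher), miR-221 and miR-222 4 of 4, miR-34 5 of 5, muscle 3 of 4, blood cell 3 of 5, endothelial 2 of 2, liver 2 of 3 (1 higher), neuronal 3 of 4 (1 higher), chromosome 19 4 of 10 (2 higher, and 8 lower with library totals), miR-320 1 of 5 and the exosome list 6 of 13 (2 higher). Mirtrons were higher for 7 of 10 and lower for 2 (5 and 4 with library totals), and epithelial markers higher for 2 of 3 and lower for 1 (0 and 2 with library totals). Every one of these counts was the same adjusted over the list alone. For the epithelial and chromosome 19 lists the median and mean differed in sign.

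The interaction asked whether the Ang change differed between exosomes and cells. It did for 278 of 1835 names, with 183 relatively higher in exosomes and 95 lower. miR-519c-3p rose in exosomes and fell in cells (interaction log2 1.85, SE 0.145, adjusted p = 1.56e-07), as did miR-3614-3p (1.66, SE 0.124). miR-510-3p, the abundant X-linked name, fell in cells and went from 1326 ± 40.7 to 2460 ± 7.69 CPM in exosomes (interaction log2 1.62, SE 0.12). miR-3972 had a 2.01-fold interaction (SE of log2 0.094). miR-552-3p had one of log2 0.57, which did not pass with library totals or limma-voom, nor without cell Ang replicate 3, cell Con replicate 2 or 3, exosomes Ang replicate 2 or exosomes Con replicate 2. In the opposite sense, miR-4699-3p rose in cells (log2 0.66) and fell in exosomes, and miR-3922-5p did likewise (interaction log2 -2.15, SE 0.264).

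In the chromosome 14 cluster 10 of 54 members had a higher Ang change in exosomes and 1 a lower, miR-382-5p (log2 -1.18). miR-654-5p (0.70) and miR-370-3p (0.60) were among those higher. Adjusted over the list alone the counts were 10 and 2, and camera gave adjusted p = 0.0774 (adjusted p = 0.995 with an estimated correlation). The direction depended on scaling: 14 and 1 passed with RLE size factors and 1 and 4 with library totals, and miR-370-3p lost its call with the latter. RLE size factors moved the median of all names by 0.106 and gave 250 higher and 77 lower over all names, library totals moved it by -0.32 and gave 93 higher of 315, and DESeq2 gave 251 and 66.

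For the other lists the interaction passed for few members, and no list passed camera. The miR-320 family had 2 of 5 higher and none lower under all 3 scalings. The miR-23/27/24 clusters had 3 of 11 higher and 1 lower (1 and 1 with library totals). The fragment list had 3 of 22 higher and 3 lower (0 and 7 with library totals), the chromosome 19 cluster 2 and 2 of 10, mirtrons 2 and 2 of 11 (0 and 2 with library totals), hypertrophy-promoting members 2 higher of 19 (1 with library totals), and the exosome list 1 higher and 3 lower of 16. Of 13 fibrosis members, 7 inflammation members and 10 miR-15/16 members, 1 each was higher. Among 14 hypertrophy-opposing and 6 neuronal members miR-9-5p was lower. Among 7 blood cell members miR-451a was lower, among 4 liver members miR-122-5p, among 2 endothelial members miR-126-3p and among 9 let-7 members let-7c-5p, and these 4 calls ended without cell Ang replicate 2. Adjusted over the list alone, 3 blood cell, 4 exosome and 4 miR-23/27/24 members passed in the same sense and no miR-15/16 member did. The muscle, epithelial, miR-17, miR-29, miR-30 and miR-34 lists and the cluster of miR-221 and miR-222 had no member past the threshold. With library totals the medians of the hypertrophy-promoting, inflammation, liver, neuronal, miR-15/16, miR-17, miR-23/27/24, miR-30 and miR-34 lists and of the miR-221 and miR-222 cluster turned below 0. With RLE size factors those of the chromosome 19, let-7, fragment, mirtron and muscle lists turned above it. Sign differed between median, mean or camera direction for the liver, neuronal, miR-15/16, miR-34 and chromosome 19 lists.

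Across 1081 names tested in both compartments, the Ang changes in cells and exosomes had Pearson r = -0.131 and Spearman rho = -0.06, and names are not independent replicates. Of the names past the threshold, 12 were higher in both (7.33 for independent lists), 15 lower in both (10.1) and 28 opposite (17.5). Of 100 relabellings of Con and Ang within compartments, 22 gave an r as far from 0.

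**Figure D4:**
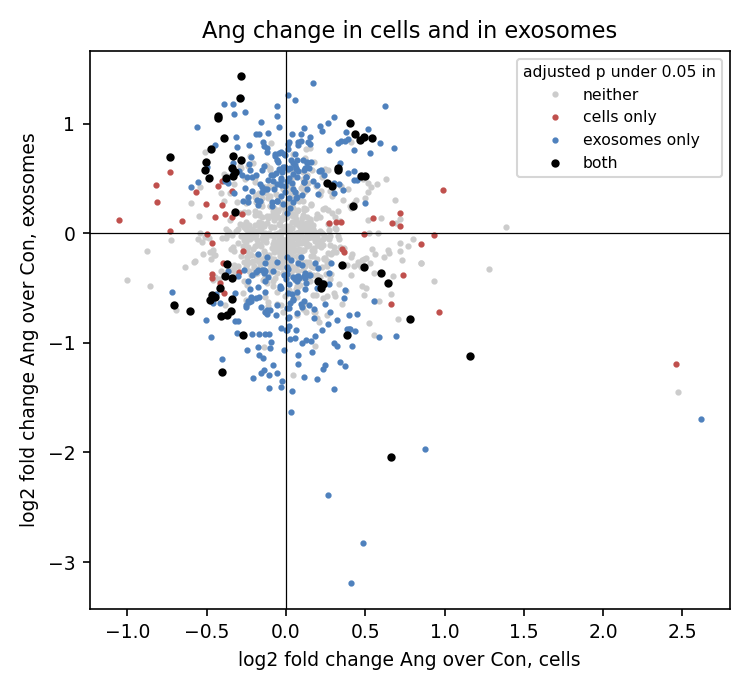
Log2 fold change of Ang over Con in exosomes against that in cells; each point is a miRNA name tested in both, coloured by where its adjusted p was under 0.05. Of the names past it in both compartments, 12 were higher in both, 15 lower in both and 28 opposite.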

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

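The tests of the 3 patterns below were chosen after the main results were seen, and those of serum miRNAs and of the cell library Ang replicate 2 also after the values they use. The Ang change differed between exosomes and cells for 278 names, which brought the largest such differences here. Higher in exosomes relative to cells were miR-548m (interaction log2 4.78), let-7a-3p (3.20), miR-651-5p (2.32), miR-3668 (1.98), miR-519c-3p (1.85), miR-6824-5p (1.72), miR-10525-3p (1.67), miR-3614-3p (1.66), miR-5581-3p (1.66) and miR-6816-3p (1.65). Lower were miR-122-5p (-5.91), miR-451a (-5.81), miR-126-3p (-3.52), miR-148a-3p (-3.48), miR-450a-2-3p (-3.17), let-7c-5p (-2.72), miR-4699-3p (-2.56), miR-1285-3p (-2.53), miR-491-3p (-2.36) and miR-3922-5p (-2.15). For miR-548m, let-7a-3p, miR-651-5p, miR-3668 and miR-491-3p the exosome libraries of Con and Ang held only 0 and 5, 1 and 11, 4 and 13, 9 and 26, and 22 and 3 counts, so the fitted values depend on the prior count. The calls of miR-451a, miR-122-5p, miR-126-3p, let-7c-5p, miR-548m and miR-651-5p ended without cell Ang replicate 2, among other libraries. Those of miR-148a-3p (without exosomes Con replicate 2 or 3 or Ang replicate 1 or 3), let-7a-3p (without exosomes Con replicate 2 or 3 or Ang replicate 2) and miR-491-3p (without any of several libraries) also ended. Without cell Ang replicate 2 and exosomes Con replicate 1 together 250 names passed, and of these names miR-451a, miR-548m and miR-651-5p did not. In exosomes Con replicate 1 miR-122-5p stood at 8.74 CPM, against 123 and 157 in the other Con and 4.30 to 18.8 in the Ang libraries. Its removal leaves only the Con libraries high in such names. The fit therefore cannot show that miR-122-5p, miR-126-3p or let-7c-5p hold without outlying libraries. With limma-voom the calls of miR-122-5p, miR-451a, miR-126-3p, miR-148a-3p, let-7c-5p and miR-491-3p ended, with DESeq2 that of miR-148a-3p and with library totals that of miR-651-5p. Of 100 relabellings of Con and Ang, the real labels included, 1 gave as many interaction calls; the highest other gave 205. The 8 others that kept the exosome libraries split as deposited gave 162 to 205 calls and the remaining 91 gave 0 to 2.

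Names higher in exosomes than in cells in Con had hairpin arms of higher GC content, with a mean of 61.2% against 48.4% for lower names, and r = 0.499 with the log2 difference. After a GC trend was removed per library, 78.8% of the higher names that were still tested passed in the same direction, so GC content is not the whole cause. Arms of 3.43% of the higher names and 2.45% of the lower names shared a 16-nt word with another annotated small RNA, which cannot tell, since the 28S and 18S rRNA and cytoplasmic tRNA sequences were not at hand. Blood cell and liver miRNAs held at most 0.153% of UMIs in any exosome library. Neither miR-552-3p nor miR-3972 is on those lists, so this share cannot tell whether either name came from serum. The extraction kit, which differed between cells and exosomes, could not be told apart from the compartment, and no biological explanation was tested.

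Ang against Con calls in exosomes were set against 3 technical explanations. Shares are of the calls still tested under each setting, out of 408. With a GC trend removed 349 of 390 (89.5%) remained in the same direction. With counts thinned to the smallest total 287 of 374 (76.7%) did, and with miR-552-3p and miR-3972 left out 381 of 405 (94.1%). None of these is therefore the whole cause. TMM already trims such leading names, which makes the last a mild test. Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05; 1 of 10, the real one, gave as many calls, and the highest other gave 0. The same held, 1 of 10 with the highest other at 0, for Ang against Con in cells and for exosomes against cells in Con and in Ang.

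Blood, liver and endothelial miRNAs were high in the cell library Ang replicate 2. Carry-over from exosome libraries was excluded, as miR-552-3p stood at 96.7 CPM there against 102 and 78.0 in the other Ang cell libraries. Of the names that stood apart in this library, 66.7%, or 8 of 12, belonged to the blood cell, liver and endothelial lists. These names are the ones that drew attention to the library, so their share does not decide whether RNA from blood or serum was the source, which stays open. In only 5.88% of list members of at least 10 CPM, 1 of 17, did both other Ang cell libraries lie above all Con cell libraries. A rise shared by every Ang cell library was thus absent for most members. Some members were near the floor in the other Ang cell libraries, such as miR-122-5p (8.2 and 7.8 CPM) and miR-451a (10.2 and 3.9 CPM), and cannot be ranked reliably there. The test was also set after these values were seen. It cannot exclude a response to Ang in this library alone, so Ang treatment as the source stays open. Blood cell and liver lists together held 0.738% of UMIs in this library.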

How the results depend on the processing

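Values under each alternative were counted for the 10 largest changes each way, the most abundant names of each group and list members printed here. Some of these names are not printed above. Direction and side of the threshold were kept by 2957 values, and 236 were weaker, 19 stronger and 13 reversed. The labels were first computed for all 510 results under the naming rule (8203 same, 404 weaker, 121 stronger, 157 reversed) and narrowed afterwards to this set. Of its called names, 16 of 27 in cells, 11 of 46 in exosomes and 10 of 26 for the interaction lost their call without some library. For exosomes against cells 0 of 49 did in Con and 0 of 31 in Ang. For lists, 58 were the same, 40 weaker and 2 reversed. With each library left out, calls in cells ran from 38 to 97, in exosomes from 312 to 422, for exosomes against cells from 1346 to 1479 in Con and 1300 to 1417 in Ang, and for the interaction from 218 to 286.

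The change of let-7a-5p in cells, near 0, reversed with RLE size factors (log2 -0.0028), DESeq2 (-0.0029), no filter (-0.0202), a mean of at least 10 CPM (-0.022), all 12 libraries (-0.047) and a GC trend removed (-0.030), and ran from -0.047 to 0.079 with each library left out. In cells miR-142-3p ran from -0.25 to 3.15 and miR-486-5p from -0.77 to 3.03, both lowest without Ang replicate 2. With a GC trend removed, miR-16-5p in Con stood at 0.58 and miR-510-3p in Ang at 0.43 for exosomes against cells. With library totals the median of the fragment list was -0.0512 in Con and -0.30 in Ang. Apart from that library, the cause was not tested.

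Names detected at 10 counts were 1579 in cells Con, 1635 in cells Ang, 1233 in exosomes Con and 1122 in exosomes Ang, and thinned to the smallest total 2583 in cells Con, 2020 in exosomes Con and 1966 in exosomes Ang. The correlation of Ang changes was -0.124 (Spearman rho -0.0011) at 100 CPM or more. For exosomes against cells in Con 0 lists passed camera with an estimated correlation and 0 with library totals, and in Ang 0 and 2. Deviations from the group means had correlations from -0.0478 to 0.11 between libraries that shared a replicate number and from -0.132 to 0.0822 between others. Among cells Ang, exosomes Con and exosomes Ang, shared numbers gave 0.0695 to 0.11 for replicates 1 and 2, and -0.0411 to -0.011 for replicate 3. The numbers were not taken as pairs, but the overlapping ranges do not decide whether they are. A replicate block gave 132 calls in cells, 398 in exosomes, 1398 and 1345 for exosomes against cells in Con and Ang, 252 for the interaction (220 blocked by culture), and 5 lists past camera in cells. These were the blood cell (camera adjusted p = 2.51e-05), hypertrophy-opposing (adjusted p = 0.00557), miR-320 and exosome (adjusted p = 0.0173 each) and let-7 lists (adjusted p = 0.0445). All but miR-320 hold members raised in cells Ang replicate 2, among them miR-142-3p, miR-486-5p and let-7c-5p. For exosomes against cells in Con, 7 of the 9 lists past camera stayed past it with the block. Among names printed the block ended the calls of miR-210-3p in exosomes, of miR-548m and miR-651-5p in the interaction and, by culture, also of miR-491-3p, and no other. Thinned to the smallest total, exosomes had 300 calls. DESeq2 gave 91 in cells and 293 in exosomes, and limma-voom 107 and 396.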

Other observations

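The test of hairpin arms was chosen after the differences between exosomes and cells were seen, and its prediction was written before it was run. Counts that come from the hairpin carrying the name should move its 5p and 3p arms together. Across hairpins with both arms tested, the arms' log2 differences between exosomes and cells in Con had Pearson r = 0.316, with 0.155 for names numbered below 1000 and 0.273 for names numbered from 1000, which leaves the question undecided. For miR-552, the 3p arm led exosomes while the 5p arm held 11 to 25 counts in cell libraries and 0 to 3 in exosome libraries.

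Names numbered from 1000, which were described later, held 71.9% of UMIs in exosomes Con and 49.9% in cells Con. Of such names 533 were higher and 390 lower in exosomes Con than in cells, against 137 higher and 365 lower for names numbered below 1000. Of 100 relabellings of Con and Ang within compartments, 22 gave a correlation of the Ang changes between cells and exosomes as far from 0 as the real one, and the highest other was 0.24. The hypertrophy-promoting list held 4.68% of UMIs in cells Con and 0.264% in exosomes Con, and the fibrosis list 7.36% and 0.434%.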
